A study of Mus musculus with 12 samples.

How the data were processed

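The series holds 12 RNA sequencing libraries of mouse tongue organoids, stranded and poly(A)-selected with TruSeq kits from RNA prepared with a Qiagen kit, per the labels' protocols. The values used were the deposited table of raw counts, which holds 55367 genes in 12 columns. Per the submitters' processing notes, reads were handled with STAR, featureCounts and the hg38 genome, with no version given; the deposited counts carry mouse gene symbols, and 96.2% of the symbols match exactly 1 gene of the mouse annotation GENCODE M21. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes were not told apart, and a gene with near-identical copies is named as uncertain. Samples were read from the column names, which equal the sample titles apart from punctuation. Low counts of 2 and 4 were over-represented against 1 and 3, so counts halved and rounded were added as an alternative after this was seen.

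Libraries were grouped by line (CVP or FoP) and label (wild type or Foxe1 knock-out) into 4 arms, each line having 2 wild type libraries and 4 knock-out libraries from 2 clones in duplicate. Wild type was taken as 1 culture per line. The labels name no wild type clone, so genotype cannot be told apart from derivation of a clone. Totals were 59.3 to 73.6 M counts, so 1 count per M of the unscaled total is 59.3 to 73.6 counts in a library. Genes were filtered with filterByExpr over the 4 arms (17076 tested), scaled by TMM and fitted with the quasi-likelihood functions of edgeR 4.0.16 (robust, R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the root of its F statistic, an approximation. Comparisons were knock-out against wild type in each line, their mean, their difference, wild type FoP against wild type CVP and, from a fit of 6 groups, clone against clone and clone against wild type. CPM values used TMM-scaled library sizes.

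Gene lists written before the data were examined were tested with camera of limma 3.58.1 (preset correlation 0.01), for the 23 lists with at least 3 tested members: saliva products, gland regulators and transport, gland duct, myoepithelial, shared and type II taste, type III taste, type I and precursor taste, basal and stem, lingual keratinocyte, cell cycle, Wnt targets, Notch, Hedgehog, thyroid and palate, endoplasmic reticulum folding, p53 targets, interferon, glycolysis and hypoxia, immediate early, fibroblast, immune, endothelial, and nerve and glia. A skeletal muscle list had 2 tested members. Of sex-linked genes Xist was tested; it held 10440 to 29831 counts, and 4 Y-linked genes held at most 2 counts per library. A change was called for a list only where camera passed, and counts are also given adjusted over the list alone and with an estimated correlation. The genes named are, per line, the 8 with the largest change in each direction among called genes with a mean of at least 2 on the log2 CPM scale and with every knock-out library beyond both wild type libraries. For the mean, the difference and the wild type comparison they are 5 in each direction, and called members of the lists were named besides, with predicted genes counted and not named and 1 gene that the rule names not reported here. A group with all libraries at 0 was given a bound from a floor of 3 counts per library; other low groups have 95% counting intervals, which cover counting error alone. If both mates of a pair were counted, which the excess of counts of 2 and 4 leaves open, these intervals and the floor are too narrow. The fitted fold changes of genes near 0 depend on the prior count of edgeR.

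Alternatives were DESeq2 size factors, no filter, a stricter filter (1 CPM in 4 libraries), the DESeq2 1.42.0 Wald test, limma voom with culture as block, 6 groups, 1 line per fit, the replicate number as a block, duplicates summed per culture (3 residual degrees of freedom), a test against a 2-fold change, and each clone and each library left out, with the genes of the full filter kept. Leaving out a wild type library leaves 1 library in its arm, which is assumed to vary like the others. A DESeq2 adjusted p that is not given has no value. On simulated data with the same 4 arms, the edgeR fit recovered 88 of 100 genes changed 2-fold in CVP and 86 in FoP, with 9 and 7 false calls among 16876 unchanged genes, 96 and 97 of 100 changed 4-fold, and camera put 0 of 20 unchanged lists past p of 0.05. The changed genes were drawn from those with a mean above 0 on the log2 CPM scale, so recovery of lower genes was not measured. The simulated libraries were independent, with no effect shared by the duplicates of a culture and no correlation between genes. These false calls therefore do not measure errors from shared cultures or from lists of correlated genes. Predicted genes made up 3279 of the tested genes.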

Results

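The series measured gene expression by RNA sequencing in mouse organoids, which are cultured 3-dimensional epithelial tissues, grown from the circumvallate papilla (CVP) and the foliate papilla (FoP), the taste papillae of the posterior tongue. The question behind the comparisons was how loss of Foxe1, a forkhead transcription factor known for its part in thyroid and palate development, changes saliva gland, taste and lingual epithelial genes. Each of the 2 lines gave 3 cultures in duplicate: a wild type culture and 2 clones labelled Foxe1 knock-out, numbered 2.9 and 2.10 in the CVP line and 2.4 and 2.5 in the FoP line. The 12 libraries held between 59.3 and 73.6 M counted reads, with 21421 to 22602 genes detected at 1 read or more, and 17076 genes were expressed enough to test. Each library was kept as a sample. Duplicates share a clone or a wild type label. Wild type was taken as 1 culture per line, and no wild type library is labelled as a clone. The p-values thus measure only the spread between these samples, part of which can be technical. The first principal component took 38.3% of the variance, the next 15.4% and the one after it 10.3%. Levels are library-scaled counts (CPM) as mean ± SD over 2 wild type or 4 knock-out libraries of a line (n = 2 and n = 4), and log2 fold changes are given ± SE. A gene said to be at a value with no unit is at that log2 fold change.

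Foxe1 lies on chromosome 4 (46343609 to 46346412, plus strand, GRCm38) as a single protein-coding exon in the annotation. Its transcript did not separate the groups. In the CVP line it stood at 15.6 ± 0.366 CPM in wild type and 15.5 ± 8.85 CPM in knock-out (log2 fold change -0.01 ± 0.52, adjusted p = 0.993), and in the FoP line at 16.2 ± 0.235 and 16.3 ± 5.76 CPM (0.01 ± 0.52, adjusted p = 0.992). The clones went both ways against their own wild type. The 2 duplicates of clone 2.9 held 1527 and 1432 counts and those of clone 2.10 held 487 and 547, beside 1049 and 1144 in CVP wild type. Clone 2.4 held 1471 and 1292 and clone 2.5 held 707 and 660, beside 1124 and 989 in FoP wild type. Tested from the spread of duplicates alone, Foxe1 was higher in clones 2.9 (log2 0.57, adjusted p = 0.000172) and 2.4 (0.39, adjusted p = 0.00507) and lower in clones 2.10 (-0.98, adjusted p = 1.54e-06) and 2.5 (-0.51, adjusted p = 0.000878). A transcript count does not check an alteration that leaves the transcript in place, and the labels do not say how Foxe1 was altered. Below, "knock-out" stands for the libraries labelled so.

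**Figure D1:**
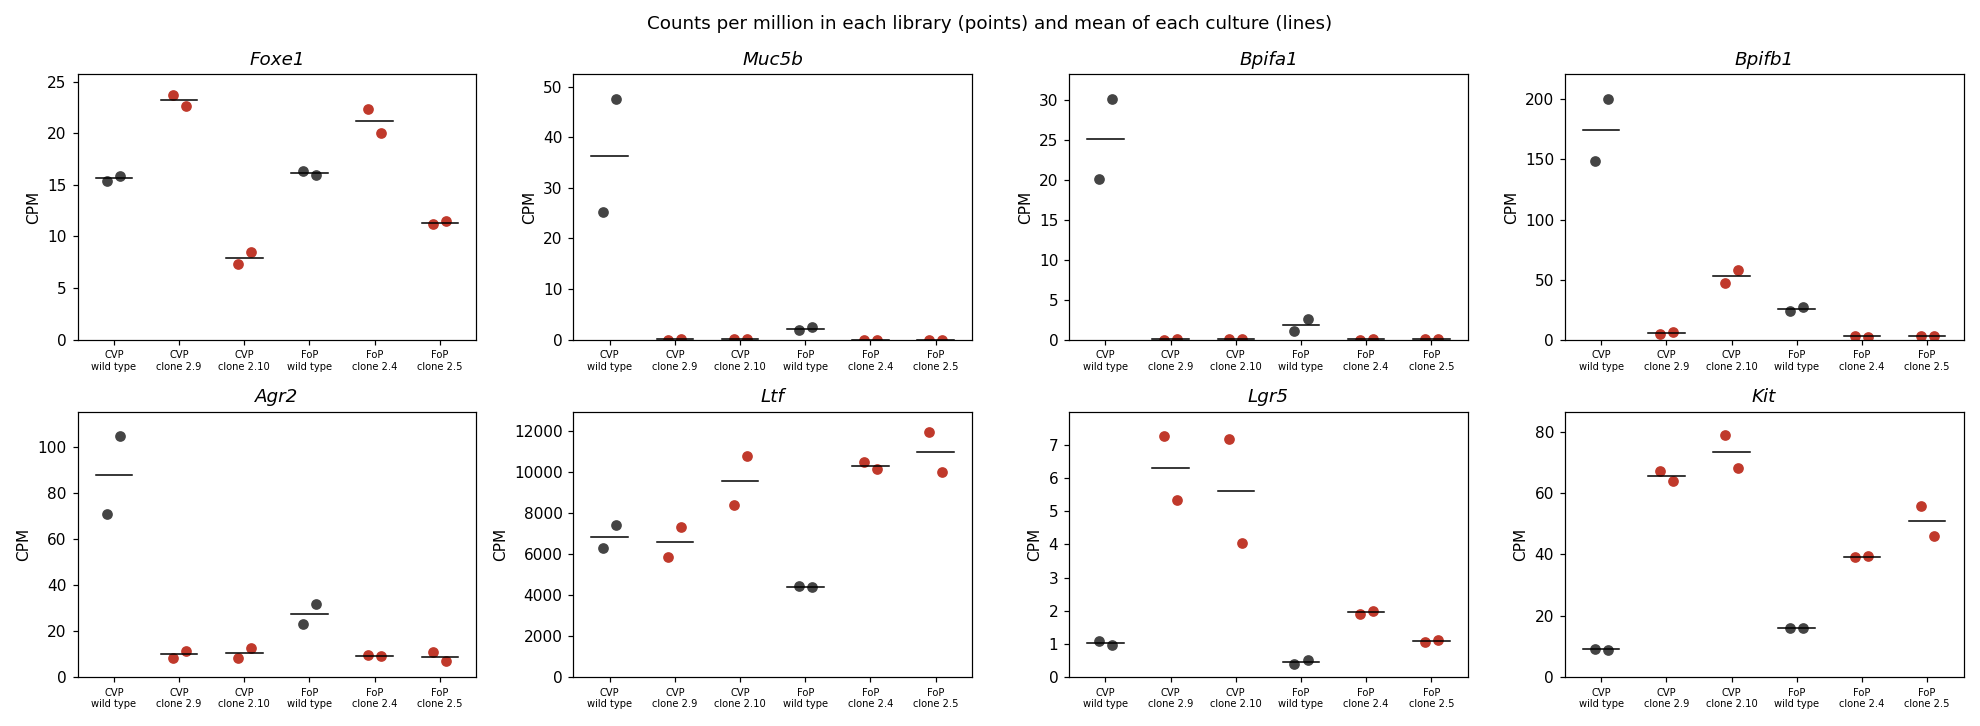
Library-scaled counts (CPM, linear axes from 0) of 8 genes in each of the 12 libraries, with grey points for wild type libraries, red points for libraries labelled knock-out and a line at the mean of each culture. Foxe1 lies between 7.33 and 23.7 CPM in the knock-out libraries, around the wild type libraries, while Muc5b and Bpifa1 lie near 0 in all 8 knock-out libraries.

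In the CVP line, the comparison of knock-out with wild type asked which genes change with loss of Foxe1 in circumvallate organoids. Lysozyme, an antimicrobial lectin, a mucin and a chemokine were among the 8 genes with the largest falls within the naming rule. Lyz2, a lysozyme, went from 23.0 ± 9.62 CPM to 0 counts in each of the 4 knock-out libraries, at least 484-fold lower against a floor of 3 counts per library. Reg3g, an antimicrobial lectin, held 4 counts in all the knock-out libraries, a wild type to knock-out ratio of 1803 (95% counting interval 704 to 6620, too narrow if both mates of a pair were counted, as are the other intervals and floors here). Bpifa1, a secreted protein of airway and oral glands, had a ratio of 818 (415 to 1896), and the gel-forming mucin Muc5b went from 36.4 ± 15.9 to 0.0658 ± 0.0408 CPM (log2 fold change -9.07 ± 0.40, adjusted p = 1.34e-07). The cell surface glycoprotein Msln fell from 420.3 ± 62.5 to 3.92 ± 2.74 CPM (log2 -6.75 ± 0.72, adjusted p = 0.000105). Ifitm1, an interferon-induced membrane protein (log2 -8.35 ± 1.11), Cybb, the catalytic subunit of the phagocyte NADPH oxidase (-6.91 ± 0.68), and the chemokine Ccl11 (-6.41 ± 0.79) fell too. Among genes that rose, the homeobox gene Shox2 held 8 counts in wild type against 3925 in knock-out, a ratio of 266 (135 to 617). The cartilage proteoglycan Acan (log2 5.83 ± 0.99), the matricellular protein Smoc1 (5.34 ± 0.67), the phosphodiesterase Pde3a (4.52 ± 0.51), Samd5 (4.37 ± 0.48), the extracellular matrix protein Spon1 (4.36 ± 0.52), Cytip (4.25 ± 0.47) and the adhesion molecule Vcam1 (3.84 ± 0.80) followed, with adjusted p from 5.81e-05 to 0.00441. Reads of Lyz2, Ifitm1 and Reg3g can be shared with close paralogs, so these values are uncertain; Lyz1 had at most 10 counts in any library. In all, 7929 of 17076 genes passed (adjusted p under 0.05, edgeR quasi-likelihood test), 4012 higher and 3917 lower, of which 1101 and 836 changed more than 2-fold and 663 were predicted genes. Every knock-out library lay beyond both wild type libraries for 5421 genes upward and 5123 downward, 61.7% of genes. Chance gives 13.3% for exchangeable libraries and up to 66.7% where duplicates are alike; clones 2.9 and 2.10, each set against the other cultures of the line after the first share was seen, gave 18.2% and 24.4%. The count was 5238 without CVP wild type 1 and 510 against a 2-fold threshold, and in limma voom with culture as block the calls of Shox2 (adjusted p = 0.144) and Acan (0.0831) were lost.

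Saliva products were lower in CVP knock-out, though not as one block. Of 53 listed saliva proteins and mucins, 20 were expressed enough to test. Of these 3 rose and 11 fell (4 and 11 adjusted over the list alone), with a median log2 fold change of -1.10 (camera adjusted p = 0.00115, adjusted p = 0.202 with an estimated correlation). Beside Bpifa1 and Muc5b, the trefoil peptide Tff2 had a wild type to knock-out ratio of 284 (144 to 658). The epithelial antibody transporter Pigr fell from 123 ± 26.2 to 5.42 ± 0.818 CPM (log2 -4.51 ± 0.73, adjusted p = 0.00109). The mucin Muc5ac (-2.69 ± 0.47), the scavenger receptor protein Dmbt1 (-1.64 ± 0.26) and lactoperoxidase, Lpo (-0.93 ± 0.17), fell too. Clusterin (Clu) rose from 308 ± 7.71 to 567 ± 80.4 CPM, and lactoferrin (Ltf), the most abundant saliva product named here, stood at 6848 ± 784 and 8101 ± 2067 CPM (log2 0.24 ± 0.18, adjusted p = 0.310). Among gland regulators and transport genes, 11 of 34 tested rose and 14 fell (11 and 15 adjusted over the list alone; camera adjusted p = 0.442). The secretory transcription factors Spdef (log2 -2.26 ± 0.27) and Elf3 (-1.52 ± 0.17) and the secretory disulfide isomerase Agr2 (-3.11 ± 0.23, from 88.0 ± 24.2 to 10.2 ± 2.23 CPM) fell. The muscarinic receptors Chrm1 (2.88 ± 0.36) and Chrm3 (1.39 ± 0.31), the chloride channel Ano1 (1.11 ± 0.13) and the chloride cotransporter Slc12a2 (0.70 ± 0.12) rose. Of duct genes, 3 of 18 tested rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.272). Cldn4 was at -2.12 ± 0.21 and Kit, a receptor tyrosine kinase, at 2.93 ± 0.15. Of myoepithelial genes, 2 of 11 tested rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.960). Their median was -0.43 and their mean 0.12, camera downward. The myosin kinase Mylk rose by 2.69 ± 0.26.

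Stem and basal markers moved apart in the CVP line. Lgr5, the R-spondin receptor that marks stem cells of the posterior tongue, rose from 1.03 ± 0.0792 to 5.95 ± 1.55 CPM (log2 2.53 ± 0.34, adjusted p = 7.54e-05). The basal keratins Krt14 (1.37 ± 0.17) and Krt5 (0.58 ± 0.11) and the hemidesmosome collagen Col17a1 (0.80 ± 0.06) rose too. Prom1 fell (-1.66 ± 0.38) and Tnfrsf19 had a wild type to knock-out ratio of 52.8 (26.3 to 124). Of the basal and stem list, 13 of 31 tested rose and 8 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.258; median 0.08, mean -0.05, camera upward). Of differentiated keratinocyte genes, fewer rose than fell: 7 of 42 tested rose and 16 fell (7 and 17 adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.596 with an estimated correlation). Krtdap fell from 28.9 ± 0.0753 to 0.804 ± 0.237 CPM (log2 -5.16 ± 0.30, adjusted p = 1.42e-06). The cornified envelope genes Sprr1b (-2.86 ± 0.38) and Ivl (-1.91 ± 0.35) and the suprabasal keratin Krt4 (-2.92 ± 0.61) fell, while the desmosomal cadherin Dsg3 rose (0.80 ± 0.08). Sprr1b belongs to a family of near-identical genes and its value is uncertain. Taste genes gave no common direction. Of shared and type II taste genes, 3 of 14 tested rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.960). Of type III genes, 1 of 7 tested rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.447), among them the sour-taste proton channel Otop1, from 2.69 ± 0.442 to 0.0512 ± 0.0676 CPM (-5.68 ± 0.74). Of type I and precursor genes, 5 of 10 tested rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.0845). The glutamate transporter Slc1a3 was at 1.92 ± 0.26 and Hes6 at 0.48 ± 0.10.

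Cell cycle genes, p53 targets and stress genes passed camera downward in CVP knock-out, while Wnt, Notch and Hedgehog genes did not pass. Of cell cycle genes, 1 of 35 tested rose and 15 fell (1 and 15 adjusted over the list alone; camera adjusted p = 0.00887, adjusted p = 0.697 with an estimated correlation). The centromere histone Cenpa was at 26.7 ± 3.01 and 9.47 ± 1.34 CPM and the kinase Bub1b at -1.25 ± 0.13. Of p53 targets, 0 of 20 tested rose and 14 fell (0 and 16 adjusted over the list alone; camera adjusted p = 0.000346, adjusted p = 0.242 with an estimated correlation). Eda2r was at -1.04 ± 0.11 and Mdm2, the p53 ubiquitin ligase, at -0.34 ± 0.05. Of endoplasmic reticulum folding genes, 2 of 22 tested rose and 13 fell (2 and 14 adjusted over the list alone; camera adjusted p = 0.000527, adjusted p = 0.242 with an estimated correlation). Edem1 was at -0.71 ± 0.05. Of glycolysis and hypoxia genes, 0 of 21 tested rose and 12 fell (0 and 12 adjusted over the list alone; camera adjusted p = 0.000433, adjusted p = 0.596 with an estimated correlation). The glucose transporter Slc2a1 was at -1.20 ± 0.13 and the growth factor Vegfa at -1.40 ± 0.23. Of immediate early genes, 1 of 15 tested rose and 10 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.00397, adjusted p = 0.355 with an estimated correlation). Jun was at -1.19 ± 0.10. Of genes tied to Foxe1 in thyroid or palate, 0 of 7 tested rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.0388, adjusted p = 0.242 with an estimated correlation). Tgfb3 was at -0.60 ± 0.13 and Duoxa1, a dual oxidase maturation factor, at -0.49 ± 0.09. Of interferon-stimulated genes, 0 of 24 tested rose and 5 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.181). Oasl1 was at -3.01 ± 0.28. Of Wnt targets, 6 of 17 tested rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.599; median 0.14, mean -0.08, camera upward), with Notum, a Wnt feedback inhibitor, at -2.49 ± 0.24. Of Notch genes, 5 of 13 tested rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.442; median 0.16, mean -0.04, camera upward), with Notch1 at -0.54 ± 0.08 and Jag1 at 0.60 ± 0.09. Of Hedgehog genes, 2 of 10 tested rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.599). Smo was at 0.42 ± 0.05. Among markers of other cell types, 0 of 5 tested rose and 3 fell (0 and 3 adjusted over the list alone) for immune cells (camera adjusted p = 0.000162, adjusted p = 0.0413 with an estimated correlation; median -2.40, and the same with Lyz2 at its bound), with Cd68 at -2.80 ± 0.18 and H2-Ab1 at -2.40 ± 0.27. For fibroblasts, 7 of 12 tested rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0388, adjusted p = 0.242 with an estimated correlation). The fibrillin Fbn1 was at 2.92 ± 0.22. For endothelium, 2 of 5 tested rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.403), and for nerve and glia, 5 of 7 tested rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.144). With an estimated correlation only the immune list kept its call among the 10 lists past camera, while 3 had an unadjusted p under 0.05 and fry, which asks whether the genes of a list move one way on balance, gave 16.

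In the FoP line, the same comparison in foliate organoids gave many of the same leading genes. Lyz2 went from 4.14 ± 1.83 CPM to 0 counts in each of the 4 knock-out libraries, at least 79.5-fold lower against a floor of 3 counts per library. Muc5b held 3 counts in all the knock-out libraries, a wild type to knock-out ratio of 183 (62.0 to 893). The chemokine Ccl11 fell from 32.5 ± 5.79 to 0.190 ± 0.120 CPM (log2 -7.37 ± 0.84, adjusted p = 0.000338) and Msln from 167 ± 21.3 to 3.20 ± 2.41 CPM (-5.71 ± 0.71, adjusted p = 0.000579). Bpifa1 (log2 -5.19 ± 0.58) and the receptor phosphatase Ptprd (-5.25 ± 1.00) fell as well, as did Gp2, a glycoprotein of zymogen granules (-4.03 ± 1.03). Reg3g, low already in wild type at 0.152 ± 0.0318 CPM, was at least 2.92-fold lower. The insulin-like growth factor binding protein Igfbp5 rose from 30.8 ± 4.77 to 594 ± 199 CPM (log2 4.27 ± 0.40, adjusted p = 0.000111). The carnitine synthesis enzyme Bbox1 (3.55 ± 0.29), the retinoic acid degrading enzyme Cyp26a1 (3.26 ± 0.33), Spon1 (2.86 ± 0.49), the Wnt inhibitor Wif1 (3.16 ± 0.60), the forkhead gene Foxf2 (2.74 ± 0.37), Shox2 (3.84 ± 1.01) and the matrix protein Matn4 (2.74 ± 0.80) rose. In all, 4921 of 17076 genes passed the edgeR test, 2301 higher and 2620 lower, of which 416 and 555 changed more than 2-fold and 274 were predicted genes. The split was less even in other settings. Tested against a 2-fold change, 41 genes were higher and 146 lower, and with limma voom and culture as block 1404 were higher and 2103 lower. Groups did not overlap for 4082 genes upward and 4411 downward, 49.7% of genes, with the same chance values, and clones 2.4 and 2.5 set against the other cultures gave 25.8% and 28.6%. The count was 2719 without FoP wild type 1, 2668 without FoP wild type 2 and 187 against a 2-fold threshold. Without those libraries in turn the adjusted p was 0.132 and 0.101 for Shox2, 0.0916 and 0.0594 for Reg3g, 0.0580 and 0.0886 for Gp2 and 0.156 and 0.167 for Matn4, with 0.0521 for Wif1 without FoP wild type 1 and 0.0634 and 0.0611 for Matn4 without clone 2.5 duplicates 1 and 2.

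In the FoP line the saliva list leaned lower by its median, while the most abundant products named here rose. Of the list, 4 of 20 tested rose and 9 fell (4 and 10 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 0.00573, adjusted p = 0.137 with an estimated correlation). Dmbt1 went from 9.58 ± 2.25 to 0.974 ± 0.280 CPM (log2 -3.29 ± 0.29, adjusted p = 3.34e-05). Lactoferrin rose from 4412 ± 35.3 to 10658 ± 889 CPM (1.27 ± 0.19, adjusted p = 0.000554) and clusterin by 0.79 ± 0.17. The saliva protein Slpi lay at 241 and 222 CPM in wild type and 509 to 677 CPM in knock-out. Wfdc2 lay at 750 and 846 CPM in wild type and 988 to 1405 CPM in knock-out. The list test gives each gene the same weight, so it does not measure the summed saliva transcripts. Of gland regulators and transport genes, 9 of 34 tested rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.241): Agr2 was at -1.60 ± 0.23, Spdef at -1.42 ± 0.29, the nucleotide receptor P2ry2 at -1.13 ± 0.17, Chrm1 at 2.98 ± 0.38 and Slc12a2 at 0.72 ± 0.12. Of duct genes, 4 of 18 tested rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.863; median -0.13, mean 0.03, camera upward), with Cldn4 at -1.18 ± 0.21 and Kit at 15.9 ± 0.00418 CPM in wild type and 45.1 ± 7.86 CPM in knock-out. Of myoepithelial genes, 2 of 11 tested rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.389). Mylk was at 3.22 ± 0.29. Lgr5 was at 1.72 ± 0.35 and Col17a1 at 0.61 ± 0.06, while Krt14 (0.20 ± 0.16, adjusted p = 0.387) and Krt5 (0.11 ± 0.11, adjusted p = 0.479) did not pass. Of the basal and stem list, 9 of 31 tested rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0522; median 0.16, mean -0.08, camera upward). Of the keratinocyte list, 7 of 42 tested rose and 8 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.996; median 0.08, mean -0.27, camera downward), with Krtdap at -2.71 ± 0.26, Ivl at -1.88 ± 0.34 and the calmodulin-like Calml3 at 1.68 ± 0.26. Of shared and type II taste genes, 0 of 14 tested rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.506). Of type III genes, 1 of 7 tested rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.366), with Otop1 at a wild type to knock-out ratio of 62.4 (28.2 to 172). Of type I and precursor genes, 4 of 10 tested rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0471, adjusted p = 0.137 with an estimated correlation), with Kit among those that rose.

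Cell cycle genes gave the broadest fall of any list in the FoP line. Here 0 of 35 tested rose and 33 fell (0 and 33 adjusted over the list alone; camera adjusted p = 5.25e-43, adjusted p = 0.111 with an estimated correlation), with a median of -1.88. The mitotic genes Tpx2 (from 59.1 ± 0.0874 to 13.1 ± 1.06 CPM, log2 -2.18 ± 0.16), Bub1b (-2.08 ± 0.13), Plk1 (-1.94 ± 0.15) and Cenpa (-1.66 ± 0.11) fell. Of p53 targets, 0 of 20 tested rose and 15 fell (0 and 15 adjusted over the list alone; camera adjusted p = 1.37e-15, adjusted p = 0.0695 with an estimated correlation). Eda2r was at -1.31 ± 0.10, Dglucy at -0.76 ± 0.06 and Trp53inp1 at -0.91 ± 0.09. Of Hedgehog genes, 5 of 10 tested rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00188, adjusted p = 0.106 with an estimated correlation). The coreceptors Boc was at 0.85 ± 0.11 and Cdon at 0.75 ± 0.15 and the transducer Smo at 0.43 ± 0.05. Of glycolysis and hypoxia genes, 0 of 21 tested rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.00188, adjusted p = 0.627 with an estimated correlation). Adm was at -1.30 ± 0.25. Of endoplasmic reticulum folding genes, 1 of 22 tested rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.125). Edem1 was at -0.40 ± 0.05. Of immediate early genes, 1 of 15 tested rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.125; median 0.01, mean -0.22, camera downward), with Atf3 at -1.61 ± 0.24. Of thyroid and palate genes, 1 of 7 tested rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.928; median -0.04, mean 0.01, camera upward). Of interferon-stimulated genes, 1 of 24 tested rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.928; median 0.03, mean -0.02, camera downward). Of Wnt targets, 4 of 17 tested rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.973; median 0.10, mean -0.09, camera upward), with Tcf7 at 0.44 ± 0.07. Of Notch genes, 4 of 13 tested rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.921; median 0.10, mean -0.57, camera upward), with Notch1 at -0.64 ± 0.08. Among other cell types, 0 of 5 tested rose and 2 fell (0 and 2 adjusted over the list alone) for immune cells (camera adjusted p = 0.0188, adjusted p = 0.120 with an estimated correlation), with Cd68 at -1.57 ± 0.18; the median was -0.14. For fibroblasts, 5 of 12 tested rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.174). Pdgfra was at 1.51 ± 0.28. For endothelium, 2 of 5 tested rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.174; median -0.22, mean 0.35, camera upward), with Flt1 at 0.80 ± 0.10. For nerve and glia, 0 of 7 tested rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.945; median -0.29, mean 0.07, camera downward). Of skeletal muscle markers only 2 were tested, too few for the list test: Acta1 was at -3.11 ± 0.64 in CVP (adjusted p = 0.00157) and had an adjusted p of 0.349 in FoP, and Myh4 was called in neither line. With an estimated correlation 0 of the 7 lists past camera kept their call, 6 lists had an unadjusted p under 0.05 and fry gave 12.

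**Figure D2:**
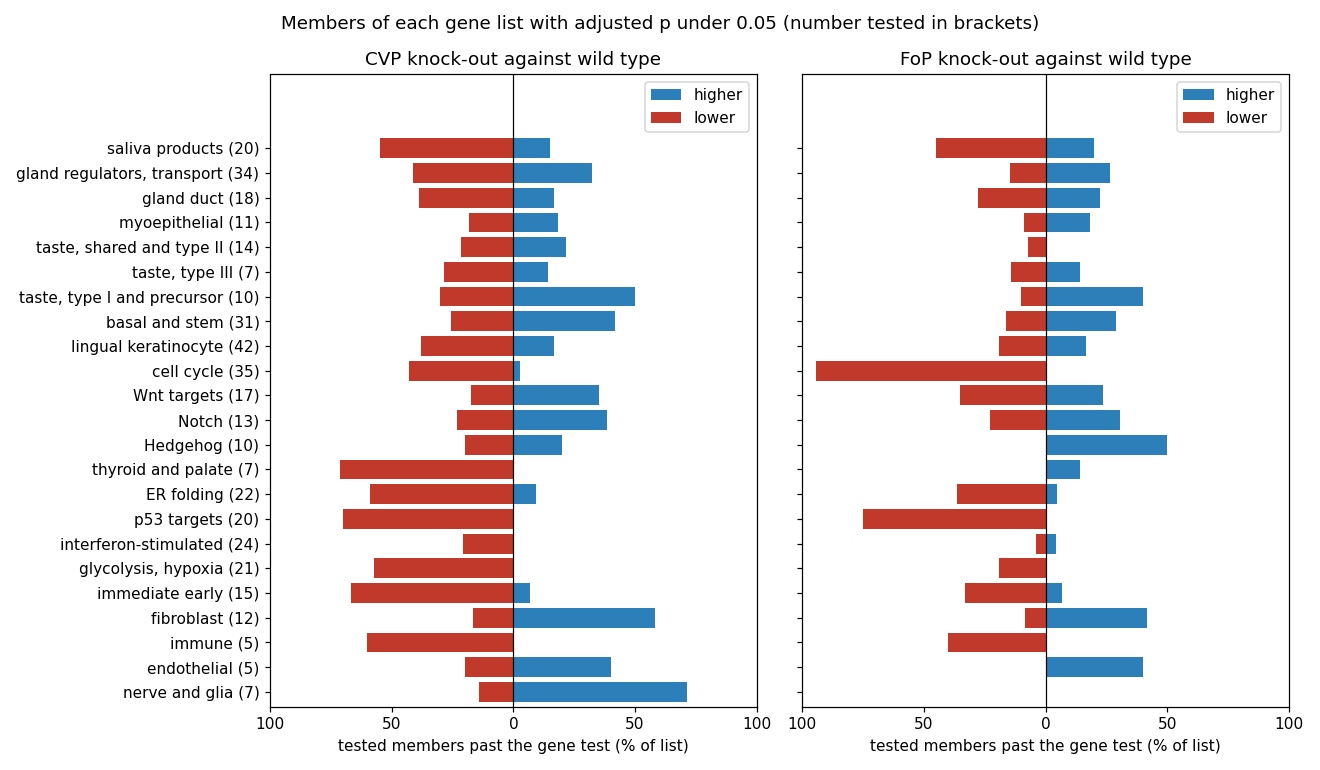
Share of the tested members of each gene list (number tested in brackets) with an adjusted p under 0.05, drawn to the right in blue where higher in knock-out and to the left in red where lower, for the CVP and the FoP line. Saliva products and p53 targets lean to the left in both lines, and 33 of 35 cell cycle genes lie to the left in FoP.

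Over both lines, the mean of the knock-out effects gave the average change in circumvallate and foliate organoids. A gene or list changed in 1 line alone can pass this test. Shox2 (log2 5.92 ± 0.75), Spon1 (3.61 ± 0.36), Bbox1 (3.44 ± 0.20), Igfbp5 (3.28 ± 0.27) and Cyp26a1 (3.21 ± 0.23) rose furthest among genes past the expression minimum of the naming rule that were called in each line and in the mean, with groups that do not overlap in either line, and Muc5b (-8.19 ± 0.32), Bpifa1 (-7.39 ± 0.40) and Ccl11 (-6.89 ± 0.58) fell, beside Lyz2 and Reg3g with their values above. In this mean 8474 genes passed the edgeR test, 4269 higher and 4205 lower. Of genes called in each line, 3493 were called in both, 3298 in the same direction and 195 in opposite directions. By direction, 1571 genes were higher in both lines where independent lists would share 541, and 1727 lower where they would share 601. The fold changes of the lines, which share no library, correlated across the 17076 genes at Pearson r = 0.49 and Spearman rho = 0.49, genes not being independent replicates. Past camera were 9 lists, 0 of them with an estimated correlation (5 lists at an unadjusted p under 0.05, 16 by fry). Lower were saliva products (camera adjusted p = 0.000422, adjusted p = 0.168 with an estimated correlation), cell cycle (camera adjusted p = 4.67e-16, adjusted p = 0.308 with an estimated correlation), p53 targets (camera adjusted p = 6.77e-10, adjusted p = 0.137 with an estimated correlation) and glycolysis and hypoxia (camera adjusted p = 0.000134, adjusted p = 0.495 with an estimated correlation). Lower too were endoplasmic reticulum folding (camera adjusted p = 0.00271, adjusted p = 0.325 with an estimated correlation), immediate early genes (camera adjusted p = 0.00931, adjusted p = 0.389 with an estimated correlation) and immune markers (camera adjusted p = 0.000134, adjusted p = 0.0589 with an estimated correlation). In FoP alone, the folding and immediate early lists did not pass (camera adjusted p = 0.125 for each). Type I and precursor taste genes (camera adjusted p = 0.0403, adjusted p = 0.168 with an estimated correlation) and fibroblast markers (camera adjusted p = 0.0441, adjusted p = 0.168 with an estimated correlation) were higher. Of 10 tested type I and precursor taste genes, 5 rose and 3 fell, and in CVP alone the list did not pass (camera adjusted p = 0.0845). Of 12 tested fibroblast markers, 7 rose and 3 fell, and in FoP alone the list did not pass (camera adjusted p = 0.174). The marker Dcn lay lower in knock-out, at 0.776 and 1.97 CPM in CVP wild type against 0.186 to 0.475 in CVP knock-out. In FoP it stood at 1.25 and 1.07 CPM in wild type and 0.232 to 0.382 in knock-out. Median, mean and camera differed in sign for gland regulators (median -0.07, mean 0.06), myoepithelial (median -0.21, mean 0.28), basal and stem (median 0.09, mean -0.06), Wnt (median 0.11, mean -0.09), Notch (median 0.17, mean -0.30) and endothelial genes (median -0.14, mean 0.23). With duplicates summed to 1 sample per culture, 2663 genes passed, 2662 of them among the 8474. In the fit that keeps each library as a sample, 403 passed against a 2-fold threshold. Same-direction genes numbered 1953 without FoP wild type 1 and 1925 without FoP wild type 2.

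The difference between the lines in the knock-out effect was tested as an interaction, as the FoP effect minus the CVP effect. Plb1, a phospholipase, rose more in CVP (log2 3.13 ± 0.11) than in FoP (0.77 ± 0.10; difference -2.36 ± 0.14, adjusted p = 7.15e-06). Chil1, a chitinase-like secreted protein, fell in CVP from 45.5 ± 16.5 to 1.01 ± 0.602 CPM and stood at 1.96 ± 0.452 and 2.07 ± 0.301 CPM in FoP (difference 5.57 ± 0.61, adjusted p = 0.000943). Pde3a (-4.80 ± 0.62), Smoc1 (-4.72 ± 0.84) and Samd5 (-3.52 ± 0.59), which rose in CVP and were not called in FoP, differed too, with adjusted p of the difference from 0.00197 to 0.00599. Ifitm1 (6.04 ± 1.51), Duoxa2 (5.41 ± 1.54), Bpifa1 (4.39 ± 1.11), Cybb (4.26 ± 0.94), Cspg4 (-5.64 ± 1.60) and Col11a1 (-3.44 ± 0.78) differed with adjusted p from 0.0179 to 0.0481. Each of these 6 calls was lost without at least 1 library: the highest adjusted p was 0.127 for Ifitm1, 0.173 for Duoxa2 and 0.0848 for Cybb without FoP wild type 1, 0.183 for Cspg4 and 0.0964 for Col11a1 without CVP wild type 1, and 0.0937 for Bpifa1 without clone 2.4 duplicate 2. Bpifa1 is near 0 in knock-out in both lines, so its difference mostly restates the wild type levels, and without clone 2.5 the FoP effect of Duoxa2 was -1.90 (adjusted p = 0.0119) and its difference 2.81 (adjusted p = 0.0121). Of cell cycle genes, 26 of 35 had a lower effect in FoP than in CVP (camera adjusted p = 1.89e-18, adjusted p = 0.361 with an estimated correlation), and p53 targets leaned the same way (camera adjusted p = 0.0369, adjusted p = 0.488 with an estimated correlation). Keratinocyte (camera adjusted p = 0.00675, adjusted p = 0.494 with an estimated correlation), thyroid and palate (camera adjusted p = 0.0105, adjusted p = 0.270 with an estimated correlation), endoplasmic reticulum folding (camera adjusted p = 0.0122, adjusted p = 0.469 with an estimated correlation) and gland regulator lists (camera adjusted p = 0.0313, adjusted p = 0.488 with an estimated correlation) were higher in the FoP effect than in the CVP effect. So were Hedgehog (camera adjusted p = 0.0299, adjusted p = 0.270 with an estimated correlation), immediate early (camera adjusted p = 0.0453, adjusted p = 0.488 with an estimated correlation) and immune lists (camera adjusted p = 0.0299, adjusted p = 0.270 with an estimated correlation), while nerve and glia markers were lower (camera adjusted p = 0.0369, adjusted p = 0.361 with an estimated correlation). In wild type FoP against wild type CVP, the median of each of these lists but keratinocyte (0.29) had the opposite sign. It was 0.82 for cell cycle genes and 0.34 for p53 targets. These list differences can therefore restate unlike wild type levels, in part or in whole. Median, mean and camera differed in sign for type III taste genes (median 0.14, mean -0.36) and basal and stem genes (median 0.03, mean -0.03). In all, 2692 genes passed, 1243 upward and 1449 downward, and 10 lists passed camera, 0 with an estimated correlation (3 at an unadjusted p under 0.05, 7 by fry). The count was 1103 without CVP wild type 1, 1532 without CVP wild type 2, 1188 without FoP wild type 1 and 1240 without FoP wild type 2.

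Wild type FoP was compared with wild type CVP to describe the wild type cultures without the knock-out. This comparison and the interaction share the wild type libraries. With wild type taken as 1 culture per line, a difference between lines cannot be told apart from a difference between cultures. Saliva products were lower in FoP: 8 of 20 members were lower and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 3.44e-09, kept with an estimated correlation at adjusted p = 0.0123). Reg3g (log2 -7.48 ± 0.66), Chil1 (-4.54 ± 0.51), Muc5b (-4.04 ± 0.39), Bpifa1 (-3.79 ± 0.52) and the tight junction gene Cldn2 (-3.03 ± 0.48) were lower in FoP. Serpinb10 (2.31 ± 0.31), Plb1 (2.04 ± 0.12), the microtubule protein Map6 (1.75 ± 0.30), Glipr2 (1.69 ± 0.20) and Zfp365 (1.51 ± 0.26) were higher. Of cell cycle genes, 13 of 35 were higher in FoP (camera adjusted p = 1.96e-18, adjusted p = 0.223 with an estimated correlation), and of p53 targets 10 of 20 (camera adjusted p = 3.44e-09, adjusted p = 0.145 with an estimated correlation). Gland regulators (camera adjusted p = 4.79e-06, adjusted p = 0.194 with an estimated correlation), duct (camera adjusted p = 0.000715, adjusted p = 0.159 with an estimated correlation), Hedgehog (camera adjusted p = 0.0339, adjusted p = 0.194 with an estimated correlation), endoplasmic reticulum folding (camera adjusted p = 0.000147, adjusted p = 0.194 with an estimated correlation) and interferon lists (camera adjusted p = 0.0339, adjusted p = 0.657 with an estimated correlation) were lower in FoP by camera and the keratinocyte list higher (camera adjusted p = 0.0182, adjusted p = 0.536 with an estimated correlation). Called lower and higher were 5 and 0 of 34 gland regulators, 4 and 1 of 18 duct, 2 and 0 of 10 Hedgehog, 6 and 1 of 22 folding, 0 and 0 of 24 interferon and 1 and 4 of 42 keratinocyte genes, and fry gave an adjusted p of 0.478 for interferon genes. Median, mean and camera differed in sign for basal and stem (median -0.12, mean 0.08), Wnt (median 0.01, mean -0.25), glycolysis and hypoxia (median -0.02, mean 0.00) and endothelial genes (median 0.01, mean -0.18). In all, 1140 genes passed, 643 higher and 497 lower in FoP. The count was 156 without CVP wild type 1, 109 without CVP wild type 2, 101 without FoP wild type 1 and 116 without FoP wild type 2. Without CVP wild type 2 the adjusted p was 0.0530 for Bpifa1, 0.0569 for Serpinb10, 0.0666 for Map6, 0.0775 for Zfp365 and 0.0575 for Cldn2; without FoP wild type 1 it was 0.0762 for Map6, 0.0703 for Zfp365 and 0.0874 for Cldn2, without FoP wild type 2 0.0688 for Cldn2, and without CVP wild type 1 0.0670 for Map6 and 0.0503 for Zfp365.

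Clones of 1 line were compared with each other to ask how far 2 knock-out clones differ. Clone 2.10 held more Bpifb1, a secreted gland protein, than clone 2.9 (log2 3.15, adjusted p = 2.63e-05) and more Matn4 (2.07, adjusted p = 1.16e-06), and less Ptprd (-3.75, adjusted p = 5.14e-06) and Foxe1 (-1.55, adjusted p = 1.34e-07). Clone 2.5 held more of the dual oxidase factor Duoxa2 than clone 2.4 (3.49, adjusted p = 1.84e-06) and less Cspg4 (-6.18, adjusted p = 1.01e-05) and Foxe1 (-0.90, adjusted p = 3.55e-05). In all, 926 genes differed between the CVP clones (493 higher and 433 lower in clone 2.10) and 1239 between the FoP clones (603 higher and 636 lower in clone 2.5), by an edgeR fit whose spread comes from duplicates. Each clone differed from its own wild type by more genes: 8040 for clone 2.9, 8474 for clone 2.10, 5535 for clone 2.4 and 5876 for clone 2.5. The CVP count was 549 without clone 2.9 duplicate 1, 601 without its duplicate 2 and 1494 without the filter on low counts. The FoP count was 512 and 645 without clone 2.4 duplicates 1 and 2, 648 and 509 without clone 2.5 duplicates 1 and 2, and 1913 without the filter.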

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

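Of the tests in this part, the sum of leukocyte transcripts and the medians per chromosome were chosen only after the result was seen. Cdkn2a and Trp53, given below, are in no gene list and outside the naming rule, so their choice was not fixed by either. Among 4 libraries of 1 arm, 5 of 245 checks set a library apart by its gap to the others, where 4 independent values would give 12.25. These were Reg3g at a log2 CPM of -3.41 in clone 2.9 duplicate 2, 22602 genes detected in clone 2.9 duplicate 1, Hes6 at a log2 CPM of 5.38 in clone 2.5 duplicate 2, Ifi27l2a at a log2 CPM of 0.25 in clone 2.4 duplicate 1, and a total of 59.3 M counts in clone 2.5 duplicate 2. The 4 libraries are 2 clones in duplicate and not independent, so 12.25 is not the chance number here. The low number of flags gives no assurance.

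The knock-out effect differed between the lines for 2692 genes by the edgeR interaction test, FoP effect minus CVP effect. A difference can also restate unlike wild type levels, as for Plb1 and Bpifa1 above. Named genes with a larger value in FoP were Ifitm1 (log2 difference 6.04), Chil1 (5.57), Duoxa2 (5.41), Tff2 (5.23), Bpifa1 (4.39), Cybb (4.26), Pigr (3.98), Wif1 (2.78), Krtdap (2.46), H2-Ab1 (2.26), Oasl1 (2.03), Igfbp5 (1.98), Agr2 (1.51), Notum (1.44), Cd68 (1.23), Wfdc2 (1.20) and Ltf (1.03). Smaller positive differences were in Boc (0.66), Dnajb9 (0.65), Slc2a1 (0.63), Duoxa1 (0.45), Hyou1 (0.37) and Edem1 (0.31). Named genes with a larger value in CVP were Cspg4 (-5.64), Pde3a (-4.80), Smoc1 (-4.72), Samd5 (-3.52), Col11a1 (-3.44), Cytip (-2.52), Plb1 (-2.36), Fbn1 (-2.17), Serpinb10 (-2.12), Dmbt1 (-1.65), Map2 (-1.45), Kit (-1.43), Map6 (-1.40) and Glipr2 (-1.31). Next came Plk1 (-1.22), Zfp365 (-1.17), Krt14 (-1.17), Tpx2 (-1.12), Bub1b (-0.83), Ano1 (-0.58), Dglucy (-0.49), Krt5 (-0.47), Dsg3 (-0.41) and Mdm2 (-0.31). By list, with 10 lists past camera and 0 with an estimated correlation, the median difference was 2.01 for immune markers, 0.48 for thyroid and palate, 0.45 for keratinocyte, 0.23 for immediate early, 0.22 for gland regulators, 0.19 for Hedgehog, 0.15 for endoplasmic reticulum folding, -0.21 for p53 targets, -0.86 for nerve and glia and -1.14 for cell cycle genes.

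Lyz2 and Cd68, of the immune list (5 of 16 members tested), and Cybb, all abundant in myeloid cells, were lower in the knock-out libraries of both lines (Cybb in FoP at adjusted p = 0.00960, and 0.0634 without FoP wild type 2). Myeloid cells in the wild type cultures could bring such transcripts, yet the sum of Ptprc, Tyrobp, Fcer1g, Csf1r and Itgam reached at most 0.292 CPM of unscaled library totals in a wild type library, where Cybb alone stood at 13.1 to 82.6 CPM on the same scale, which argues against them. Whether derivation of a clone lowers these genes cannot be told apart from loss of Foxe1, since 0 wild type libraries are labelled as clones. Expression in the epithelium itself is a hypothesis that stays open, and reads shared between Lyz2 and Lyz1 leave Cybb and Cd68 untouched.

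The p53 targets were lower in both lines while Cdkn2a, a cell cycle inhibitor gene, rose by a log2 of 2.02 (adjusted p = 1.66e-07) in CVP and 2.18 (adjusted p = 3.59e-07) in FoP in the edgeR fit. A further list of 22 p53 targets had a median log2 change of -0.15 over both lines, with 2 of 21 tested members higher and 11 lower (camera p = 0.000724; 0.0301 with an estimated correlation), so the change reaches p53 targets outside the list. Gain or loss of a whole chromosome is argued against by medians of at most 0.079 in size over 20 chromosomes and 4 clones. The lower transcripts of p53 targets, whose calls are lost with an estimated correlation (adjusted p = 0.242 in CVP and 0.0695 in FoP), may come from loss of Foxe1 or from derivation of clones, which cannot be told apart with 0 labelled wild type clones. Trp53 itself was at 0.31 in CVP (adjusted p = 0.00549) and 0.00 in FoP.

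Of 100 splits of the libraries within each line into 4 and 2, drawn from 225, 1 called as many genes over both lines as the real 8474, the real one itself, and the highest other called 3429. This excludes chance only if duplicates count as separate samples, since all but 4 of the splits part duplicates of a culture; the 3 others that keep cultures whole gave at most 2008. For gene lists, 11 of 100 splits put 9 or more past camera, the highest other 10, so chance is not excluded for the number of lists. With duplicates summed, 9 choices of a culture per line as wild type are too few for a share under 0.05: the real one, 1 of 9, gave 2663 genes and the highest other 0 (145 to 705 at an unadjusted p under 0.05, against 5982). Unequal depth is argued against by 8427 genes with every library thinned to the smallest total.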

How the results depend on the processing

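The counts halved and rounded were the only alternative chosen after the result was seen; they gave 7942 genes in CVP, 5041 in FoP, 8415 over both lines, 2869 for the difference between lines and 1215 for the wild type comparison, all within 1.5 times. DESeq2 size factors gave 7925 in CVP and 4910 in FoP, and 1 line per fit 7487 and 4774. The number of genes moved by more than 1.5 times in these settings: without a filter, 1494 between CVP clones and 1913 between FoP clones; with 6 groups, 4424 for the difference between lines and 2788 for wild type; with DESeq2, 1974 for wild type; with limma voom and culture as block (consensus correlation 0.255), 1422 for the difference and 522 for wild type; with duplicates summed per culture, 2663 over both lines. Against a 2-fold change, 510 genes passed in CVP, 187 in FoP, 403 over both lines, 8 for the difference and 5 for wild type. Camera with an estimated correlation put 1 list past the test in CVP, 0 in FoP and 0 over both lines, against 16, 12 and 16 by fry. Leaving out 1 library gave 5238 (CVP wild type 1) to 7975 genes in CVP, 2668 (FoP wild type 2; 2719 without FoP wild type 1) to 5079 in FoP, 7014 to 8441 over both lines, 1103 (CVP wild type 1) to 2903 for the difference, 101 (FoP wild type 1) to 1235 for wild type, 1925 (FoP wild type 2) to 3311 changed the same way in both lines, 549 (clone 2.9 duplicate 1) to 1026 between CVP clones and 509 (clone 2.5 duplicate 2) to 1627 between FoP clones. It left 7 to 12 lists past camera in CVP, 6 to 8 in FoP and 7 to 10 over both lines. The replicate numbers were not taken to pair the samples, since only 3 of 15 pairs of groups correlate above 0.1 (from -0.23 to 0.48). These 3 are the clones of CVP (0.48), the clones of FoP (0.29) and the wild types (0.20), so a pairing within each of these sets is not excluded. With the replicate number as a block, 7633 genes passed in CVP, 4627 in FoP, 8250 over both lines, 2368 for the difference, 895 for wild type, 895 between CVP clones and 1143 between FoP clones, with 3088 changed the same way in both lines and 10, 8 and 9 lists past camera, which moved no count by more than 1.5 times. That block is a single shift common to all groups, so it cannot test a pairing that differs between the sets. Values of genes not called in the fits above changed sign in some settings. In CVP these were Foxe1 with a stricter filter (0.000884) and without clone 2.10 (0.57), and Wif1 (-0.54) and Ltf (-0.0510) without clone 2.10; without 1 library Foxe1 ranged from -0.29 to 0.23. In FoP they were, with 6 groups, Foxe1 (-0.0607), Duoxa2 (-0.15) and Duox2 (-0.72), and with limma voom and culture as block Foxe1 (-0.0465), Duoxa2 (-0.22) and Duox2 (-0.78). Without clone 2.4 they were Foxe1 (-0.50), Vcam1 (-0.0926), Col11a1 (0.0514), Map6 (-0.20), Pigr (0.25), Krt4 (0.48), Duoxa1 (0.0400) and H2-Ab1 (0.19). Without clone 2.5 they were Pde3a (0.24), Krt5 (-0.0333), Tgfb3 (0.00634), Duoxa2 (-1.90, adjusted p = 0.0119) and Duox2 (-2.39, adjusted p = 0.0161). Without 1 library the FoP values ranged from -0.18 to 0.15 for Foxe1, -0.63 to 0.76 for Krt4, -0.14 to 0.34 for Chil1, -0.64 to 0.45 for Duox2 and -0.73 to 0.0196 for Krt15. Among values of named genes that a setting tested, calls lost numbered 148 against a 2-fold change, 34 with limma voom and culture as block, 20 without a filter, 10 with 1 line per fit, 4 with the replicate number as a block, 1 with 6 groups and 0 with DESeq2 or a stricter filter. Genes without an adjusted p in a setting could not count as lost. Reg3g, Tff2 and Tnfrsf19, for example, did not pass the stricter filter and were not tested there. Leaving out a clone ended 7 (clone 2.10) to 15 (clone 2.4) such calls, and leaving out a wild type library 16 (CVP 1), 23 (CVP 2), 31 (FoP 1) and 38 (FoP 2).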

Other observations

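The gene families in this part, 22 in all, and their tests were chosen only after the result was seen. Collagens, which build the extracellular matrix, leaned upward in CVP knock-out: 13 of 33 tested rose and 2 fell (median log2 0.86, camera adjusted p = 0.00626, adjusted p = 0.104 with an estimated correlation), beside 7 of 33 tested rose and 3 fell (median log2 -0.09, camera adjusted p = 0.390) in FoP, where camera leaned upward. The fibroblast list, which holds some collagens, also went upward in CVP, with 7 of 12 tested higher and 2 lower (camera adjusted p = 0.0388, adjusted p = 0.242 with an estimated correlation). Claudins, proteins of tight junctions, leaned downward: 1 of 12 tested rose and 7 fell (median log2 -0.83, camera adjusted p = 0.00706, adjusted p = 0.104 with an estimated correlation) in CVP and 1 of 12 tested rose and 7 fell (median log2 -0.42, camera adjusted p = 0.123) in FoP, Cldn4 among those that fell. Cldn2 went the other way. It lay at 3.40 and 5.90 CPM in CVP wild type and 10.5 to 22.9 CPM in CVP knock-out. In FoP it lay at 0.538 and 0.599 CPM in wild type and 2.52 to 4.43 CPM in knock-out. Cytosolic ribosomal proteins were mostly lower in CVP and in part higher in FoP: 2 of 82 tested rose and 67 fell (median log2 -0.36, camera adjusted p = 9.97e-12, adjusted p = 0.658 with an estimated correlation) in CVP and 18 of 82 tested rose and 0 fell (median log2 0.15, camera adjusted p = 0.000288, adjusted p = 0.794 with an estimated correlation) in FoP, with the difference between lines not tested for families. Small proline-rich proteins, which harden the outer keratinocyte layer, leaned downward in CVP: 0 of 13 tested rose and 9 fell (median log2 -2.86, camera adjusted p = 0.00170, adjusted p = 0.452 with an estimated correlation), beside 1 of 13 tested rose and 5 fell (median log2 -0.75, camera adjusted p = 0.375) in FoP, though reads can be split between their copies. Antigen presentation genes of the H2 family did so too: 0 of 18 tested rose and 9 fell (median log2 -0.28, camera adjusted p = 0.0197, adjusted p = 0.452 with an estimated correlation), beside 1 of 18 tested rose and 4 fell (median log2 -0.21, camera adjusted p = 0.380) in FoP. The immune list, which holds H2-Ab1, was lower in CVP as well (camera adjusted p = 0.000162, adjusted p = 0.0413 with an estimated correlation). Semaphorins leaned downward in CVP: 1 of 18 tested rose and 8 fell (median log2 -0.45, camera adjusted p = 0.0452, adjusted p = 0.277 with an estimated correlation), beside 5 of 18 tested rose and 5 fell (median log2 0.03, camera adjusted p = 0.612) in FoP. Of glutathione S-transferases, 2 of 19 tested rose and 9 fell (median log2 -0.45, camera adjusted p = 0.0494, adjusted p = 0.452 with an estimated correlation) in CVP and 2 of 19 tested rose and 6 fell (median log2 -0.26, camera adjusted p = 0.380) in FoP. Enzymes of cholesterol synthesis leaned upward in CVP: 13 of 23 tested rose and 2 fell (median log2 0.56, camera adjusted p = 0.0440, adjusted p = 0.897 with an estimated correlation), and not in FoP, where 2 of 23 tested rose and 4 fell (median log2 -0.24, camera adjusted p = 0.357). Beta protocadherins, cell adhesion genes of neurons and epithelia, were higher in FoP: 6 of 21 tested rose and 0 fell (median log2 1.14, camera adjusted p = 0.0321, adjusted p = 0.399 with an estimated correlation), beside 4 of 21 tested rose and 0 fell (median log2 0.57, camera adjusted p = 0.174) in CVP. The directions of these medians were the same with DESeq2 size factors.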
